A study of Mus musculus with 16 samples.

How the data were processed

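RNA from liver was measured by sequencing in 16 libraries, 4 from each combination of genotype (Cyp2b-null or hCYP2B6-Tg) and sex. Per the labels, the C57BL/6 mice of both genotypes were fed a diet of 60% fat for 16 weeks, RNA was extracted with Trizol, and libraries were made with the NEB Next Ultra RNA kit. Each library's genotype and sex were taken from its title, and libraries are named here by group and by the number in the title. The labels do not state in so many words that each library is a separate animal; the protocol speaks of RNA from each treatment group with 4 per group. The p-values therefore measure the spread between these libraries, which may be partly technical. Titles also give no litter, cage, day or time of collection.

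The deposited table holds whole-number read counts per gene and library, one row per gene symbol. The submitters' processing notes name FastQC, Trimmomatic, GSNAP, Subread and edgeR and the mouse build GRCm38.p6, with no versions and no order. The strand setting and the handling of reads that map to several places are not given in the sources used here. Genes that share sequence with a close copy, such as the Cyp2a, Cyp2b, Cyp3a41, Mup and Sult2a families, and genes that overlap a transcript on the other strand, are therefore uncertain as single genes. The table has 41585 rows, of which 16032 had no count in any library. Spreadsheet software had turned 27 symbols into dates, 2 row names were repeated, and 3 empty columns were left out. RefSeq symbols of the same build matched 37085 row names, and coordinates come from that annotation. A row for the human CYP2B6 transgene was not analysed here.

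Library totals ran from 5584587 to 9672708 counts. A count of 0 in a library allows a level of up to 0.310 to 0.537 CPM (counts scaled to library size), taking 3 counts as the limit. Such limits and the 95% counting intervals of ratios cover counting error only. All 16 libraries matched their labelled sex by Xist and Ddx3y. No 2 libraries of one group looked like copies of one library: over genes with at least 20 counts in a pair, the chi-square per degree of freedom was 6.53 to 19.7 in the 24 pairs within groups. Pairs across groups were not compared in this way. The ribosomal RNA rows Rn18s-rs5 and LOC101056014 together took 2.76% to 9.31% of the counts of a library.

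Genes were filtered with edgeR's filterByExpr, which left 13470, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood F test (glmQLFit with robust estimation, two-sided) on one fit of all 16 libraries in 4 groups, with Benjamini-Hochberg adjustment over the 13470 genes and a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. The contrasts were hCYP2B6-Tg against Cyp2b-null in females and in males, the difference between those contrasts, and females against males within each genotype. CPM values use TMM-scaled library totals and are given as mean ± SD over n = 4 libraries. Rows below the filter were compared by exact permutation of the libraries, two-sided, which with 4 against 4 cannot give a p below 0.0286. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

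Lists of genes for liver pathways, hormone-dependent genes and cell types, 40 in all with 799 genes, were fixed before the data were examined, as were the tests, the genes to be named and most alternatives. The 34 lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 34 lists. Camera compares a list with the other genes. Each list was also tested with a correlation estimated from the data and with fry, which asks whether a list's genes move one way on balance. A count "adjusted over the list alone" comes from the gene test adjusted over the list's members only. List tests of the difference between the sexes and of sex itself were added after the data had been seen, with their alternatives. Median and mean log2 fold changes describe the tested members of a list.

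The genes named followed a rule. In a genotype comparison these were up to 12 genes with the largest rise and up to 12 with the largest fall among genes past the threshold, with a mean of at least 1 CPM in the higher group, with all 4 libraries of one group above all 4 of the other, and without a predicted or clone name. For the difference between the sexes the rule took up to 10 genes with the smallest p, and for sex the 5 largest in each direction. It also took the tested genes of the Cyp2b region and up to 4 members of each list with the smallest adjusted p, and, where no gene passed, the 3 with the smallest p. Genes named outside the rule are said to be so, and a few genes that the rule selects are not reported here.

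The alternatives were other scalings (RLE, library totals only), no filter or a minimum of 1 CPM in 4 libraries, DESeq2, limma voom with and without quality weights, edgeR's older quasi-likelihood method, no robust estimation, a fit of only the groups compared, a threshold of 0.1, a minimum log2 change of 1, a block for the number in the title, and leaving out each library in turn. For lists a prior count of 0.5 was also used. Leaving out the ribosomal RNA rows, and leaving out null_female 1, null_female 3 and tg_male 4 together, were added after the data had been seen. Those 3 libraries were chosen by eye and not by a rule. The scripts were tested on simulated counts with 200 changed genes: among the 67 genes changed 2-fold, the test recovered 68.7% in the female contrast, 79.1% in the male contrast, 34.3% in the difference between the sexes, 74.6% for sex in Cyp2b-null and 62.7% for sex in hCYP2B6-Tg livers.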

Results

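Liver RNA was sequenced from male and female mice of 2 genotypes after 16 weeks on a diet with 60% fat. Cyp2b-null mice lack Cyp2b genes, and hCYP2B6-Tg mice carry the human CYP2B6 gene. CYP2B enzymes are cytochrome P450 oxidases of the liver endoplasmic reticulum that metabolise drugs, steroids and unsaturated fatty acids, and the mouse genes respond to the nuclear receptor CAR. The series was made to learn what human CYP2B6 does in diet-induced obesity at the level of liver transcripts. Each combination of genotype and sex had 4 libraries, with 5584587 to 9672708 counts and 17748 to 19181 detected genes per library. Expression is given as counts scaled to library size (CPM), mean ± SD with n = 4, and changes as log2 fold changes ± standard error from edgeR.

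Sex, not genotype, was the main axis of these livers. The first principal component of 13470 tested genes carried 42.9% of the variance and separated every male from every female library, and the second carried 6.80%. With edgeR quasi-likelihood tests and Benjamini-Hochberg adjustment, 1013 genes differed by sex in Cyp2b-null livers (481 higher and 532 lower in females) and 1381 in hCYP2B6-Tg livers (632 and 749). Genotype changed 15 genes in males (7 higher and 8 lower in hCYP2B6-Tg) and 0 in females, and 6 genes differed in their genotype effect between the sexes. At unadjusted p under 0.05 there were 966 genes in males and 1022 in females, against 673.5 expected by chance among 13470. The median standard error of a log2 fold change was 0.166 for the female and 0.168 for the male contrast of the shared fit.

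**Figure D1:**
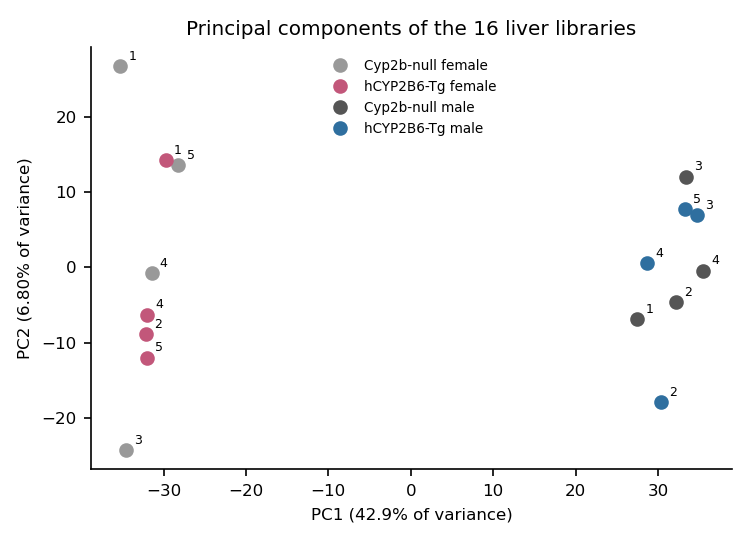
Principal components of the 16 liver libraries, with the first component on the horizontal axis and the second on the vertical axis, each with its share of variance in percent. Each point is 1 library, and males and females separate along the first component while the genotypes overlap.

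The mouse Cyp2b genes lie on chromosome 7 (GRCm38.p6) in a cluster with Cyp2a genes: Cyp2b10 at 25897658–25926624, Cyp2b13 at 26061388–26096197, Cyp2b9 at 26173350–26210661, Cyp2b23 at 26665227–26686430 and Cyp2b19 at 26757142–26772630. Cyp2b10 is the form most strongly induced by phenobarbital through CAR, and Cyp2b9 and Cyp2b13 are the female-biased forms. Which of these genes the Cyp2b-null mice lack is not given in the sources used here. All 5 fell below the expression filter and were read as counts. In the 4 Cyp2b-null female libraries Cyp2b10 had 2 counts in all, Cyp2b19 had 0 and Cyp2b23 had 0, against 26, 18 and 28 in hCYP2B6-Tg females. In males the sums were 0, 1 and 0 counts in Cyp2b-null against 33, 28 and 38 in hCYP2B6-Tg livers. Over pooled counts, Cyp2b23 was at least 9.32-fold higher in hCYP2B6-Tg females and at least 11.3-fold higher in hCYP2B6-Tg males (at least 5.48-fold without tg_male 4, which held 25 of the 38 counts), Cyp2b10 at least 9.84-fold higher in males, and Cyp2b19 at least 5.99-fold higher in females. The remaining ratios, with 95% counting intervals, were 13 (3.25–113) for Cyp2b10 in females and 25.0 (4.14–1024) for Cyp2b19 in males. For each of these 3 genes the exact two-sided permutation p was 0.0286 in each sex, the lowest that 4 against 4 libraries allow, and 0.0929 after Benjamini-Hochberg adjustment over 13 rows of the region. In an edgeR fit without the filter, Cyp2b10 passed in males (adjusted p = 0.0192) and not in females (0.423), while Cyp2b19 (0.119 in males, 0.423 in females) and Cyp2b23 (0.188 and 0.511) did not pass.

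Added together, Cyp2b10, Cyp2b19 and Cyp2b23 gave 0 or 1 count in every Cyp2b-null library, 9 to 26 in hCYP2B6-Tg females and 6 to 50 in hCYP2B6-Tg males. Their summed level in hCYP2B6-Tg livers was only 2.31 ± 0.725 CPM in females and 2.99 ± 2.23 CPM in males. Cyp2b9 was counted in both genotypes, with 16 and 41 counts in females (exact p = 0.0286, adjusted 0.0929 over the 13 rows) and 11 and 43 in males (exact p = 0.229). In males 8 of the 11 Cyp2b9 counts were in null_male 4 and 27 of the 43 in tg_male 4. Cyp2b13 had 4 and 1 counts in females and 0 and 3 in males. A count of 0 in a whole group allows up to 0.0987 CPM in Cyp2b-null females and 0.111 CPM in Cyp2b-null males. Reads assigned to one Cyp2b gene can come from another with a similar sequence, so the split among the 5 is uncertain. Reads of the human CYP2B6 transgene could also have been assigned to these mouse genes, since the build named is that of the mouse. The counts in hCYP2B6-Tg livers are thus not shown to come from the mouse genes.

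**Figure D2:**
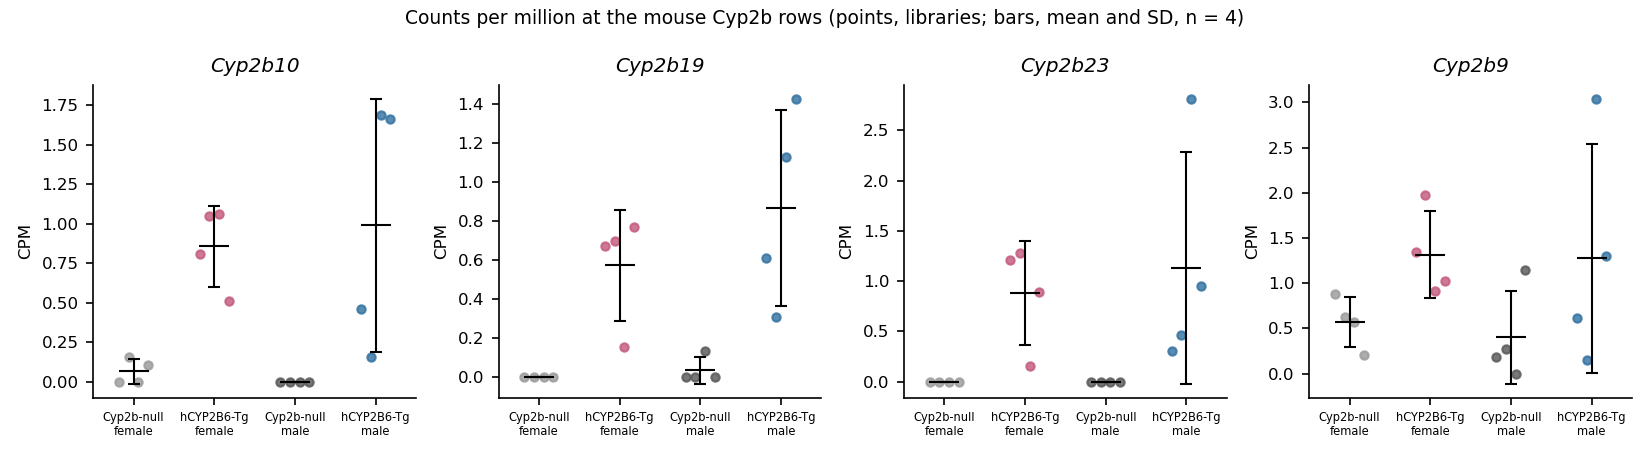
Reads assigned to Cyp2b10, Cyp2b19, Cyp2b23 and Cyp2b9, with the 4 groups on the horizontal axis and CPM on the vertical axis. Each point is 1 library, bars give mean and SD, and levels of Cyp2b10, Cyp2b19 and Cyp2b23 were near 0 in Cyp2b-null livers of both sexes.

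The Cyp2a, Cyp2f and Cyp2g genes around the cluster encode P450 enzymes for steroids, coumarin and small toxic molecules, and could in principle be disturbed by a deletion next to them. In females 0 of the 6 tested neighbours changed (edgeR adjusted p 0.809 to 0.982). In males all 6 had higher estimates in hCYP2B6-Tg livers, and as a list they rose (camera adjusted p = 0.00107, and adjusted p = 0.185 with an estimated correlation), with a median log2 fold change of 0.32. Cyp2a4 (7:26307192–26315088), a testosterone 15α-hydroxylase that males express at a low level, was the only member to pass when adjusted over the list alone, and 0 passed over all genes. Cyp2a4 had a log2 fold change of 1.04 ± 0.29 in males (edgeR adjusted p = 0.370), from 57.1 ± 25.7 to 117 ± 33.3 CPM. The coumarin hydroxylase gene Cyp2a5 (0.43 ± 0.24), Cyp2a12 (0.14), Cyp2a22 (0.74, and 0.13 without tg_male 4), Cyp2f2 (0.16) and Cyp2g1 (0.20, and -0.029 without null_male 3) had adjusted p of 0.726 to 0.971 in males.

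In males, the genes that differed between hCYP2B6-Tg and Cyp2b-null livers were of mixed function, and some of them act in growth factor signalling, nutrient sensing or the circadian clock. Ciart represses the clock activator complex, Nampt makes the NAD precursor that sirtuins depend on, and Fnip2 binds folliculin and AMPK. Egfr, the receptor for epidermal growth factor, is expressed more in male than in female mouse liver, and Dusp6 is a phosphatase that shuts off ERK below it.

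Rhobtb1, which encodes an adaptor of a ubiquitin ligase (10:69151058–69291791), had the smallest p of the genes higher in hCYP2B6-Tg males: it rose by 0.74 ± 0.11 (edgeR adjusted p = 0.00791), from 43.1 ± 3.72 to 72.3 ± 5.23 CPM. Fnip2 (3:79455971–79568151) rose by 0.93 ± 0.15 and Rasgef1b, an exchange factor for Rap2 (5:99217420–99252927), by 1.08 ± 0.18 (edgeR adjusted p = 0.0196 for both). Fnip2 went from 34.1 ± 4.88 to 64.9 ± 10.5 CPM and Rasgef1b from 6.02 ± 1.28 to 12.8 ± 1.07 CPM. The largest rise was in Ciart (3:95878500–95882257), by 1.70 ± 0.34 (adjusted p = 0.0437), from 2.16 ± 1.03 to 7.35 ± 1.54 CPM. Ccdc141, a coiled-coil protein of the centrosome (2:77009902–77173769), rose by 0.88 ± 0.18 (adjusted p = 0.0437). Nampt (12:32820335–32853369) rose by 0.40 ± 0.08 (edgeR adjusted p = 0.0488), from 77.3 ± 4.35 to 102 ± 2.36 CPM.

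Among genes lower in hCYP2B6-Tg males, Egfr (11:16752203–16913907) had by far the highest expression. Egfr fell from 405 ± 32.7 to 159 ± 19.6 CPM, with a log2 fold change of -1.35 ± 0.21 (edgeR adjusted p = 0.0299). The ERK phosphatase gene Dusp6 (10:99263231–99267489) had -0.83 ± 0.14, the H3K9 demethylase gene Phf8 (X:151520641–151633859) -0.74 ± 0.13 and the calcium sensor gene Ncald (15:37366175–37792519) -0.61 ± 0.11, all at an adjusted p of 0.0299. Pim1, a kinase gene induced by STAT5 (17:29490785–29496111), fell from 24.9 ± 3.24 to 13.7 ± 2.30 CPM (-0.86 ± 0.17, adjusted p = 0.0404). The mismatch repair gene Pms1 (1:53189187–53297031) had -1.06 ± 0.21 (adjusted p = 0.0437) and the H3K36 methyltransferase gene Whsc1l1 -0.59 ± 0.11 (adjusted p = 0.0390). The largest fall, -2.34 ± 0.45 (adjusted p = 0.0390), was in Tnk2os (16:32665223–32668197), a long non-coding RNA antisense to Tnk2. Tnk2os was scarce, with 1.76 ± 0.275 CPM in Cyp2b-null and 0.326 ± 0.127 CPM in hCYP2B6-Tg males, and reads from Tnk2 itself cannot be told apart here without the strand setting.

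**Figure D3:**
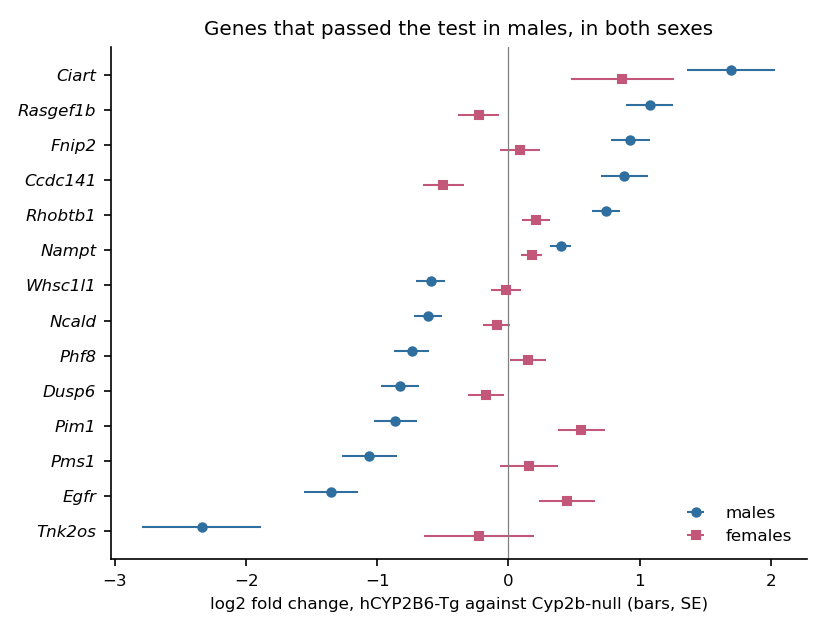
Log2 fold change, hCYP2B6-Tg over Cyp2b-null, on the horizontal axis for the named genes that passed in males, on the vertical axis. Points are estimates in males (circles) and females (squares) with bars of 1 standard error, and the female estimates lie nearer to 0 or on the other side of it. The genes were picked by their values in males, which favours larger estimates there, so the figure does not test a difference between the sexes.

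The remaining gene past the threshold, with a clone name, was D930015E06Rik (0.67, edgeR adjusted p = 0.0437). Of the 15 genes, 9 had the same sign in females, and 4 had an unadjusted p under 0.05 there, Ciart and Nampt with the same sign and Ccdc141 and Pim1 with the opposite sign. Across all tested genes the genotype effects of males and females were unrelated (r = -0.025). The male count depended on single libraries: it was 8 without null_male 1, 3 without null_male 2 or null_male 3, 2 without null_male 4, 6 without tg_male 2, 5 without tg_male 3, and 2 without tg_male 4 or tg_male 5. Rhobtb1 passed without any one library (adjusted p at most 0.0452). Rasgef1b was lost without null_male 3 (0.0835), null_male 4 (0.0562) or tg_male 5 (0.0685), and Fnip2 without null_male 2 (0.0745), null_male 3 (0.0835), tg_male 2 (0.0568) or tg_male 4 (0.0619). Ciart, Nampt, Tnk2os, Egfr and Pim1 were lost without any one of null_male 1, 2, 3, 4 or tg_male 2, 3, 4, 5, with Egfr at 0.0536 to 0.0976, Ciart at 0.0619 to 0.173, Nampt at 0.0794 to 0.190, Tnk2os at 0.0743 to 0.175 and Pim1 at 0.0612 to 0.183. The Egfr estimate stayed at -1.43 to -1.30 throughout. In other settings at the same threshold Egfr was lost in 0 of 13, Pim1 in 3 of 13, Nampt in 5 of 13, Tnk2os in 5 of 12 and Ciart in 6 of 12. With the same 8 omissions Dusp6 was kept only without null_male 2 or null_male 3 (others 0.0619 to 0.0866), Ccdc141 only without null_male 1 (others 0.0643 to 0.215), Ncald only without tg_male 2 (others 0.0612 to 0.0875) and Whsc1l1 only without null_male 3 (others 0.0619 to 0.153). Pms1 and Phf8 were kept only without tg_male 3, at 0.0794 to 0.152 and 0.0545 to 0.124 otherwise. Without null_female 1, null_female 3 and tg_male 4, chosen by eye after the data had been seen, 28 genes passed in males (17 higher and 11 lower), 11 of them among the 15. Marker genes of other tissues, with Cyp2s1 from the Cyp2b region, were uneven among the male libraries (named after their values were seen). The pancreatic gene Ctrb1 had 159 counts in null_male 4 and 0 in the other 7 male libraries, while the acinar genes Cpa1, Pnlip and Clps had 0 in all 16 libraries. The fat cell gene Adipoq had 7 counts in null_male 4, 3 in null_male 2, 1 in null_male 3 and 0 in hCYP2B6-Tg males, and Cyp2s1 had 47 in null_male 4 against 0 to 11 in the other male libraries. The fat cell genes Cfd (336 counts in Cyp2b-null and 424 in hCYP2B6-Tg males), Cidea (22 and 42) and Fabp4 (192 and 263) went the other way. Of these counts tg_male 4 held 266, 22 and 123. Lep, Plin1, Retn and Aqp7 had at most 4 counts in males of either genotype, more of them in Cyp2b-null.

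Lists of genes for making fatty acids and cholesterol were higher in hCYP2B6-Tg than in Cyp2b-null males with the preset correlation of camera, but not with an estimated one, and 0 of their genes passed over all genes. Lipogenesis turns surplus acetyl-CoA into fatty acids and triglyceride under insulin, SREBP1c and ChREBP. Cholesterol synthesis and uptake are run by SREBP2. The lipogenesis list rose in males (camera adjusted p = 1.13e-05, and adjusted p = 0.499 with an estimated correlation), with 15 of 19 tested genes higher and a median log2 fold change of 0.61. Of the lipogenesis genes 0 passed over all genes and 3 when adjusted over the list alone. These were Me1, which supplies NADPH (0.72 ± 0.21, edgeR adjusted p = 0.370), Acaca, the first committed enzyme (0.61 ± 0.19, adjusted p = 0.411), and the pyruvate kinase gene Pklr (0.46 ± 0.15, adjusted p = 0.411). Me1 averaged 115 ± 16.5 CPM in Cyp2b-null and 189 ± 40.7 CPM in hCYP2B6-Tg males. Thrsp, a lipogenic regulator, had the larger but less certain estimate of 1.56 ± 0.54 (edgeR adjusted p = 0.537), with 343 ± 107 and 1013 ± 411 CPM.

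The cholesterol synthesis list rose alike (camera adjusted p = 1.13e-05, and adjusted p = 0.499 with an estimated correlation), with 21 of 24 genes higher, a median of 0.24, 0 genes passing over all genes and 1 over the list alone. The list of gluconeogenesis, glycolysis and insulin signalling rose (camera adjusted p = 0.000246, and adjusted p = 0.185 with an estimated correlation), with 21 of 28 higher and a median of 0.15. Again 0 of its genes passed over all genes, and 3 passed over the list alone. Among them were the glucose carrier gene Slc2a2 (0.30 ± 0.08, edgeR adjusted p = 0.273; 380 ± 17.4 and 467 ± 32.8 CPM) and the gluconeogenic regulator Foxo1 (0.40 ± 0.12, adjusted p = 0.307). Oxidative phosphorylation genes, which make the respiratory chain and ATP synthase, had small estimates in males, nearly all of one sign, none of which passed. In that list 29 of 31 were higher, with a median of 0.10 (camera adjusted p = 0.000194, and adjusted p = 0.499 with an estimated correlation). The largest evidence in it was for the ATP synthase gene Atp5o (0.27 ± 0.11, edgeR adjusted p = 0.607), and 0 of 31 passed either over all genes or over the list alone.

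Genes of the circadian clock, which times liver metabolism, included the largest rise among the 15 genes. Repressors of the E-box arm of the clock peak together in the evening in mouse liver, opposite to Arntl and Nfil3, so a shift in either direction moves the groups apart. The circadian list rose (camera adjusted p = 0.000469, and adjusted p = 0.499 with an estimated correlation), with 14 of 19 genes higher and a median of 0.37. Ciart passed over all genes and 7 passed over the list alone. The repressor gene Bhlhe40 had 0.67 ± 0.14 (edgeR adjusted p = 0.0986), with 84.5 ± 10.1 and 135 ± 14.7 CPM, and the period gene Per1 had 1.24 ± 0.30 (adjusted p = 0.227), with 11 ± 2.26 and 26.4 ± 8.07 CPM. Nfil3, a repressor of the opposite phase, had -0.54 ± 0.15 (edgeR adjusted p = 0.283).

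Sex-dependent, zonal and endothelial genes made up the other lists that changed in males. Male-biased liver genes depend on pulsatile growth hormone and STAT5b, pericentral genes on WNT from central vein endothelium, and periportal genes carry urea synthesis and gluconeogenesis. Male-biased liver genes fell (camera adjusted p = 0.00429, and adjusted p = 0.499 with an estimated correlation), with 19 of 22 lower and a median of -0.33. Egfr was the 1 gene of the list to pass over all genes and over the list alone. The 3β-hydroxysteroid dehydrogenase gene Hsd3b5 (-1.22 ± 0.51, edgeR adjusted p = 0.607) and the urinary pheromone carrier gene Mup7 (-1.23 ± 0.60, adjusted p = 0.712) did not pass. Pericentral genes fell (camera adjusted p = 0.0113, and adjusted p = 0.499 with an estimated correlation; median -0.10), with 12 of 14 lower and 1 over the list alone, the WNT target and repressor Tbx3 (-1.06 ± 0.29, edgeR adjusted p = 0.307; 41.6 ± 8.15 and 19.6 ± 8.97 CPM). The WNT feedback gene Axin2 had -0.57 ± 0.22 (edgeR adjusted p = 0.555). Periportal genes rose (camera adjusted p = 0.00749, and adjusted p = 0.499 with an estimated correlation; median 0.16), with 13 of 17 higher and 0 passing by either adjustment. They included the lipid droplet enzyme gene Hsd17b13 (0.40 ± 0.12, edgeR adjusted p = 0.359) and the urea cycle gene Arg1 (0.23 ± 0.10, adjusted p = 0.658). Markers of sinusoidal endothelium rose (camera adjusted p = 0.0170, and adjusted p = 0.720 with an estimated correlation; median 0.13), with 13 of 16 higher and 0 passing by either adjustment, and with the hyaluronan receptor gene Lyve1 at 0.79 ± 0.27 (edgeR adjusted p = 0.483).

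These 10 lists of 34 in males held with the preset correlation of camera only: 0 passed with the estimated correlation and 0 with fry, and the other 24 had adjusted p of 0.0966 to 0.974. The male-biased list was lost without null_male 2 (adjusted p = 0.0925), null_male 4 (0.101) or tg_male 4 (0.222), the pericentral list without null_male 2 (0.119), the periportal list without null_male 2 (0.119) or tg_male 3 (0.0959), and the endothelial list without null_male 2 (0.123) or tg_male 2 (0.0516). Without null_male 2 the count of lists was 6.

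In females 0 of 13470 genes passed by edgeR and 1022 had an unadjusted p under 0.05, and lists for protein folding, the clock, lipid oxidation, lipid synthesis and matrix passed only with the preset correlation of camera, not with an estimated one or fry. Heat shock proteins refold proteins in the cytosol, and the unfolded protein response raises chaperones of the endoplasmic reticulum, where CYP2B6 resides. The smallest adjusted p of a single gene by edgeR was 0.186, shared by Marveld1, Fam160a1, St5 and Loxl4, and the count was 0 with limma voom and 10 with DESeq2. Marveld1, a membrane protein gene, had 0.70 ± 0.14 (17.4 ± 2.44 and 28.4 ± 5.0 CPM; DESeq2 adjusted p = 0.0332). Fam160a1, of the endosome motor adaptor family, had -1.20 ± 0.24 (6.97 ± 1.75 and 2.96 ± 0.515 CPM; DESeq2 adjusted p = 0.0332). St5, a regulator of Rab13, had -0.71 ± 0.14 (39.7 ± 8.57 and 24.2 ± 1.64 CPM; DESeq2 adjusted p = 0.0336). Outside the naming rule, the lysyl oxidase gene Loxl4 had the largest estimate of the 4, -1.97 ± 0.39 (7.26 ± 4.36 and 1.76 ± 0.359 CPM; DESeq2 adjusted p = 0.0332), and Derl3, which moves misfolded proteins out of the endoplasmic reticulum, had the smallest DESeq2 adjusted p, 0.00132, with 3.57 ± 0.86 and an adjusted p of 0.448 in edgeR. Its level was 0.706 ± 0.370 CPM in Cyp2b-null and 7.93 ± 8.31 CPM in hCYP2B6-Tg females, a spread as large as the mean. Leaving out null_female 1 gave 1 gene, E2f8 (1.20, edgeR adjusted p = 0.0251), and leaving out tg_female 1 gave 1 gene, Rassf3 (-0.72, adjusted p = 0.00130), both named after their values were seen.

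The unfolded protein response list rose in females (camera adjusted p = 1.96e-07, and adjusted p = 0.665 with an estimated correlation), with 22 of 25 genes higher and a median of 0.32. No member passed by either adjustment. The disulfide isomerase gene Pdia6 and the co-chaperone gene Dnajc3 each had 0.32 ± 0.11 (edgeR adjusted p = 0.549). The heat shock list rose with all 14 genes higher and a median of 0.36 (camera adjusted p = 4.40e-07, and adjusted p = 0.599 with an estimated correlation). Of these 0 passed over all genes and 3 over the list alone: the small chaperone gene Hspb1 (1.43 ± 0.39, edgeR adjusted p = 0.448; 5.35 ± 1.22 and 14.2 ± 9.21 CPM), the HSP90 partner gene Chordc1 (0.48 ± 0.16, adjusted p = 0.549) and the HSP110 family gene Hspa4l (0.54 ± 0.19, adjusted p = 0.549).

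The circadian list rose in females as in males (camera adjusted p = 8.15e-05, and adjusted p = 0.599 with an estimated correlation), with 15 of 19 higher and a median of 0.36. The clock repressor Bhlhe41 was the 1 gene to pass over the list alone, with 1.92 ± 0.49 (edgeR adjusted p = 0.448; 0.495 ± 0.341 and 2.06 ± 0.704 CPM), and 0 passed over all genes. Per2 had 0.80 ± 0.27 (adjusted p = 0.551), and the clock activator Arntl had -0.93 ± 0.33 (adjusted p = 0.566). Targets of PPARα, the receptor that turns on fatty acid oxidation, rose by a small median of 0.08 (camera adjusted p = 0.000184, and adjusted p = 0.786 with an estimated correlation), with 35 of 40 higher. Of these targets 0 passed over all genes and 1 over the list alone, the peroxisomal thiolase gene Acaa1a (0.35 ± 0.09, edgeR adjusted p = 0.448; 138 ± 14.7 and 175 ± 16.8 CPM). The fatty acid ω-hydroxylase gene Cyp4a31 had 0.67 ± 0.24 (edgeR adjusted p = 0.551).

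Lipogenesis genes fell in females (camera adjusted p = 0.0128, and adjusted p = 0.786 with an estimated correlation), with 14 of 19 lower and a median of -0.12. Here 0 passed over all genes and 1 over the list alone, Elovl5, which elongates polyunsaturated fatty acids (-0.46 ± 0.12, edgeR adjusted p = 0.448; 1163 ± 83.8 and 845 ± 126 CPM). The triglyceride lipase gene Pnpla3 had -1.43 ± 0.55 (adjusted p = 0.589). Fibrosis and matrix genes fell (camera adjusted p = 0.0471, and adjusted p = 0.786 with an estimated correlation), with 20 of 24 lower, a median of -0.17 and 0 passing by either adjustment. The collagen genes Col3a1 and Col5a1 had -0.42 ± 0.20 and -0.39 ± 0.20 (edgeR adjusted p = 0.664 and 0.670). The lipogenesis list was lost without null_female 5 (adjusted p = 0.407) or tg_female 4 (0.301), and the fibrosis list without null_female 4 (0.231), null_female 5 (0.208), tg_female 2 (0.198), tg_female 4 (0.117) or tg_female 5 (0.0725). In females 6 of 34 lists thus passed with the preset correlation and 0 with the estimated correlation or fry, and the other 28 had adjusted p of 0.0617 to 0.963. With the number in the title as a block, the lists of PPARα targets (0.0507), lipogenesis (0.105) and fibrosis (0.0873) did not pass. The fibrosis list was also lost with RLE scaling (0.0530), with no filter (0.0636), with a prior count of 0.5 (0.0503) and without the ribosomal RNA rows (0.0525). The count of lists was 11 without null_female 1, 9 without null_female 3 and 12 without null_female 1, null_female 3 and tg_male 4.

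Some transcripts that differ by sex in Cyp2b-null livers were alike or reversed in the hCYP2B6-Tg livers. In Cyp2b-null livers Pim1 and Egfr were higher in males, while in hCYP2B6-Tg livers Egfr was still higher in males (-0.75 in females over males, edgeR adjusted p = 0.0349) and Pim1 did not differ detectably (adjusted p = 0.728). E2f8 drives the polyploidy of hepatocytes, and Wipf3 and Ablim3 bind the actin cytoskeleton. The genotype effect differed between the sexes in 6 of 13470 genes (edgeR, Benjamini-Hochberg), with 3 more positive and 3 more negative in females, and 1037 genes had an unadjusted p under 0.05. Pim1 (1.42 ± 0.24, female minus male), Ccdc141 (-1.38 ± 0.24), Wipf3 (-1.35 ± 0.24) and Rasgef1b (-1.30 ± 0.24) had an adjusted p of 0.0421. E2f8 (1.92 ± 0.33) and Ablim3 (1.07 ± 0.20) had an adjusted p of 0.0445. E2f8 went from 11.4 ± 5.34 to 20.1 ± 3.93 CPM in females and from 20.5 ± 3.22 to 9.97 ± 1.80 CPM in males, and Pim1 from 10.3 ± 3.11 to 14.9 ± 1.83 and from 24.9 ± 3.24 to 13.7 ± 2.30 CPM. Wipf3 went from 13.2 ± 3.27 to 8.48 ± 0.925 CPM in females and from 9.14 ± 1.23 to 15 ± 2.48 CPM in males. For Egfr the difference was 1.80 ± 0.30 (adjusted p = 0.0539), with 69.0 ± 18.2 and 94.2 ± 27.5 CPM in females. No difference was shown for Rhobtb1 (adjusted p = 0.339), Fnip2 (0.302) or Ciart (0.757), so their changes in males are not shown to be absent from females.

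All 6 calls were close to the threshold. The count was 0 without null_female 4, tg_female 2, tg_female 4, tg_female 5, null_male 2, null_male 3, null_male 4, tg_male 3, tg_male 4 or tg_male 5, then 3 without null_female 1 or tg_male 2, 5 without null_male 1, 6 without null_female 3 or null_female 5, and 12 without tg_female 1. E2f8, for which the lost omissions gave 0.0852 to 0.170, stayed without null_female 1 (adjusted p = 0.000143), null_female 5, tg_female 1 or null_male 1. Ccdc141 stayed only without null_female 1, 3 or 5, tg_female 1 or null_male 1 (0.0534 to 0.138 in the other omissions), and Pim1 only without null_female 3 or 5, tg_female 1, null_male 1 or tg_male 2 (0.0534 to 0.138). Wipf3 stayed only without null_female 1 or 5, tg_female 1 or tg_male 2 (0.0534 to 0.147), Rasgef1b only without null_female 3 or 5 or tg_female 1 (0.0535 to 0.150) and Ablim3 only without null_female 5 or tg_female 1 (0.0672 to 0.170). Where 5 or fewer genes passed, those outside the 6 were Nrp1 and Keg1 without null_male 1 and Dlc1 without tg_male 2, named after their values were seen. With edgeR, DESeq2 or limma voom 0 genes passed in both sexes.

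Lipogenesis had the smallest p among 12 lists whose genotype effect differed between the sexes by camera with the preset correlation, and none of the 12 passed with an estimated one. The lipogenesis list had a lower genotype effect in females than in males (camera adjusted p = 6.89e-07, and adjusted p = 0.499 with an estimated correlation), with a median difference of -0.90. Elovl5 had -0.75 ± 0.17 (edgeR adjusted p = 0.264) and Me1 -0.95 ± 0.29 (adjusted p = 0.457). Cholesterol synthesis (camera adjusted p = 0.000401, median -0.28), periportal genes (0.00120, -0.29) and oxidative phosphorylation (0.00144, -0.11) were also lower in females. The unfolded protein response (0.000401, 0.37) and male-biased genes (0.000636, 0.50) were higher. With an estimated correlation the adjusted p was 0.589 for cholesterol synthesis, oxidative phosphorylation and the unfolded protein response, and 0.499 for the periportal and male-biased lists. Xbp1, a transcription factor of the unfolded protein response, had 0.54 ± 0.21 (edgeR adjusted p = 0.573).

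Another 6 lists differed between the sexes by camera but depended on single libraries. Heat shock proteins (adjusted p = 0.00885, median 0.34) were lost without tg_female 5 (0.0740) or tg_male 4 (0.0502). Endothelial markers (0.00885, -0.29) were lost without null_female 1 (0.0896), null_female 5 (0.0838) or tg_female 4 (0.10), and pericentral genes (0.0145, 0.20) without null_female 1 (0.231) or tg_female 4 (0.10). The gluconeogenesis list (0.0213, -0.15) was lost without null_female 3, null_female 4, tg_female 1, tg_female 4, null_male 3, null_male 4 or tg_male 3 (0.0510 to 0.0731). Fibrosis genes (0.0290, -0.22) were lost without null_female 4, null_female 5, tg_female 2, tg_female 4, tg_female 5, null_male 3, tg_male 3, tg_male 4 or tg_male 5 (0.0539 to 0.357), and hepatocyte markers (0.0385, -0.13) without null_female 3, null_female 5, tg_female 1, tg_female 4, null_male 1, tg_male 2, tg_male 3 or tg_male 5 (0.0574 to 0.0993). With an estimated correlation the adjusted p was 0.589 for heat shock, pericentral and fibrosis genes, 0.634 for endothelial markers and 0.499 for gluconeogenesis and hepatocyte markers. Without null_female 1, null_female 3 and tg_male 4 the adjusted p was 0.115 for the unfolded protein response, 0.60 for heat shock proteins, 0.145 for male-biased genes and 0.0811 for pericentral genes. The clock list did not differ (camera adjusted p = 0.856), and its median (-0.01) and mean (0.02) had opposite signs.

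The genes with the largest differences between female and male livers included genes of steroid and xenobiotic metabolism and genes of the sex chromosomes. Sulfotransferases of the Sult2a and Sult3a families conjugate steroids and bile acids, and Cyp4a12 enzymes, the Mup pheromone carriers and Elovl3 are known to depend on male growth hormone pulses, which were not measured here. In Cyp2b-null livers, Sult2a1 reached 476 ± 139 CPM in females and had 0 counts in males, at least 4206-fold. Sult2a3 was at least 925-fold and Sult2a5 at least 521-fold higher in females, and ratios with 95% counting intervals were 6634 (1836–54780) for Sult2a2 and 10787 (2986–89079) for the X-inactivation RNA Xist. Higher in males were Hsd3b5 by a ratio of 2044 (565–16881), the arachidonic acid hydroxylase gene Cyp4a12b at least 210-fold, and the Y-linked genes Ddx3y by 2821 (506–111470), Eif2s3y by 1604 (287–63406) and Uty at least 179-fold. Hsd3b5 passed with edgeR (adjusted p = 1.70e-06) but not with limma voom (adjusted p = 0.125). It was lost in 2 of 13 other settings in all, at an adjusted p of up to 0.147. Sequences of the Sult2a genes are alike, so the split among them is uncertain.

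In hCYP2B6-Tg livers, the P450 gene Cyp3a41a reached 882 ± 584 CPM in females and 0.134 CPM in males (log2 fold change 12.53 ± 0.77, edgeR adjusted p = 1.20e-10). Sult2a3 was at least 985-fold higher, Sult3a1 at least 602-fold (62.1 ± 44.6 CPM in females), Sult2a2 by a ratio of 6998 (1937–57790) and the plasma glycoprotein gene A1bg by 2651 (907–12856). Sult3a1 did not pass when only the 2 groups were fitted (edgeR adjusted p = 0.0537). Cyp4a12a was higher in males by a ratio of 2995 (537–118318), Ddx3y by 1490 (412–12311) and Eif2s3y by 1756 (315–69398), Uty at least 201-fold and the Y-linked demethylase gene Kdm5d at least 164-fold. Of the genes that differed by sex, 597 passed in the same direction in both genotypes (257 higher and 340 lower in females, against 22.6 and 29.6 expected by chance). The log2 fold changes of the genotypes were correlated across genes (r = 0.820). The rank correlation was lower, at 0.458, as r gives more weight to the genes with the largest differences. E2f8, singled out after its values were seen, alone passed in opposite directions, with -0.91 ± 0.24 in Cyp2b-null (edgeR adjusted p = 0.0213) and 1.01 ± 0.24 in hCYP2B6-Tg livers (adjusted p = 0.00888). Leaving out any one library gave 749 to 938 genes in Cyp2b-null and 981 to 1282 in hCYP2B6-Tg livers.

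**Figure D4:**
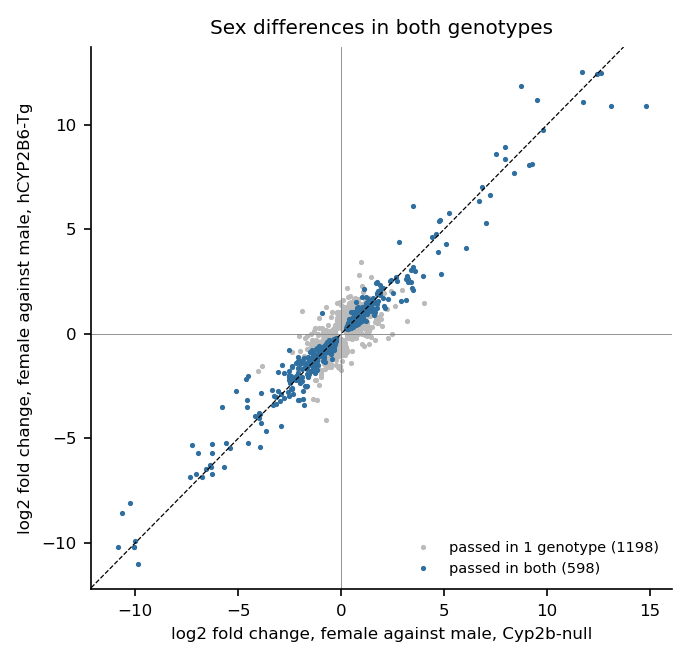
Log2 fold change of females over males for each gene that passed in at least 1 genotype, in Cyp2b-null livers on the horizontal axis and in hCYP2B6-Tg livers on the vertical axis. Each point is 1 gene, and genes that passed in both genotypes lie along the diagonal with the exception of E2f8.

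Lists fixed from known sex-biased liver genes separated the sexes in both genotypes. Of 32 tested female-biased genes 27 passed in Cyp2b-null and 28 in hCYP2B6-Tg livers, all higher in females (29 and 30 over the list alone), with medians of 4.11 and 3.43 (camera adjusted p = 1.72e-57 and 8.42e-53). They included the P450 gene Cyp2c40 (4.77 ± 0.16, edgeR adjusted p = 5.50e-15 in Cyp2b-null and 5.40 ± 0.16, adjusted p = 1.07e-15 in hCYP2B6-Tg). Of 22 male-biased genes 20 passed in each genotype, all lower in females (22 and 21 over the list alone), with medians of -4.40 and -3.70 (camera adjusted p = 1.77e-48 and 6.09e-38). The pheromone carrier gene Mup20 had -6.57 ± 0.30 and -6.47 ± 0.30, and the elongase gene Elovl3 -6.27 ± 0.32 and -5.68 ± 0.32. Other Cyp2c, Cyp2d and Cyp3a genes (camera adjusted p = 6.19e-08 and 8.49e-10), neighbours of the Cyp2b genes (4.91e-07 and 3.14e-05) and genes of the X and Y chromosomes (1.83e-12 and 6.41e-12) also passed in both genotypes. These 5 lists passed in both genotypes with an estimated correlation (adjusted p at most 0.0259). Among the neighbours, Cyp2a4 was higher in females by 3.40 ± 0.31 (edgeR adjusted p = 9.35e-06) in Cyp2b-null and 2.48 ± 0.29 (adjusted p = 0.000106) in hCYP2B6-Tg livers. The median of the X and Y list moved from -10.04 to -7.48 in Cyp2b-null and from -10.18 to -7.65 in hCYP2B6-Tg livers when genes without counts were set to their bounds.

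Of 34 lists, 17 differed by sex in Cyp2b-null and 19 in hCYP2B6-Tg livers by camera, 16 and 17 with fry, and 5 and 6 with an estimated correlation. Immune and lipid genes were among them. Interferon genes were higher in females in both genotypes (camera adjusted p = 1.43e-08 and 2.88e-08, and adjusted p = 0.175 and 0.194 with an estimated correlation), with 9 and 10 of 30 passing, such as the guanylate-binding gene Gbp3 (1.30 ± 0.20, edgeR adjusted p = 0.000109 in Cyp2b-null). Over the list alone 12 and 18 interferon genes passed. Kupffer cell markers were higher in females (camera adjusted p = 1.08e-05 and 0.00458, and adjusted p = 0.232 and 0.424 with an estimated correlation), with 6 of 18 passing in Cyp2b-null and 2 in hCYP2B6-Tg livers. The complement receptor gene Vsig4 had 0.90 ± 0.13 (edgeR adjusted p = 5.80e-05 in Cyp2b-null) and the lectin gene Clec4f 0.58 ± 0.11 (adjusted p = 0.000766). Lists of stellate cell and erythroid markers also passed by sex in both genotypes by camera, and those of hepatocyte markers and fibrosis in Cyp2b-null livers. With an estimated correlation the camera adjusted p was 0.160 and 0.300 for stellate, 0.344 and 0.300 for erythroid, 0.227 for hepatocyte and 0.293 for fibrosis genes. Genes of fatty acid uptake and lipid droplets were lower in females (camera adjusted p = 0.00121 and 3.74e-05, and adjusted p = 0.0975 and 0.0302 with an estimated correlation), with 7 of 29 passing lower in Cyp2b-null and 10 in hCYP2B6-Tg livers. The droplet genes Fitm1 and Cidec had -2.54 ± 0.20 (edgeR adjusted p = 9.35e-08) and -2.10 ± 0.37 (adjusted p = 0.000967) in Cyp2b-null livers. Adipocyte markers were also lower in females (camera adjusted p = 0.0187 and 0.0449, and adjusted p = 0.232 and 0.300 with an estimated correlation; medians -0.42 and -0.29), with 2 of 7 passing in each genotype. That list was lost without null_female 1 (0.0783) or null_male 1 (0.0643) in Cyp2b-null, and without tg_female 1 (0.110), tg_male 2 (0.0570) or tg_male 4 (0.0793) in hCYP2B6-Tg livers. It was also lost with a block for the number in the title (0.0530 in Cyp2b-null and 0.105 in hCYP2B6-Tg). In hCYP2B6-Tg livers RLE scaling (0.0514) and no filter (0.150) ended the camera call as well. Fat cells also express Cidec, so the droplet genes are not specific to hepatocytes. Alas2, the erythroid aminolevulinate synthase gene, was lower in females by -2.59 ± 0.12 (edgeR adjusted p = 1.05e-13). In Cyp2b-null livers Cfd, an adipocyte protease gene, was lower in females by a ratio of 125 (42.5–611).

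Lists of lipid synthesis passed by sex in hCYP2B6-Tg livers with the preset correlation of camera, but not with an estimated one. Lipogenesis genes were lower in hCYP2B6-Tg females than males (camera adjusted p = 1.09e-07, and adjusted p = 0.234 with an estimated correlation), with 7 of 19 passing lower and 1 higher, 13 over the list alone and a median of -0.83. In Cyp2b-null livers the list did not differ (camera adjusted p = 0.528; median 0.07 and mean -0.21, opposite in sign). Me1 had -1.22 ± 0.21 (edgeR adjusted p = 0.00174), the acyltransferase gene Gpam -1.27 ± 0.23 (adjusted p = 0.00316) and Elovl5 -0.66 ± 0.12 (adjusted p = 0.000908) in hCYP2B6-Tg livers. Cholesterol genes were lower in hCYP2B6-Tg females (camera adjusted p = 1.22e-06, and adjusted p = 0.366 with an estimated correlation), with 8 of 24 passing lower and 1 higher, 16 over the list alone and a median of -0.55. The sterol carrier gene Stard4 had -0.59 ± 0.10 (edgeR adjusted p = 0.000256). Genes of polyunsaturated fatty acid and oxylipin metabolism, substrates of which CYP2B6 oxidises, were slightly lower in hCYP2B6-Tg females (camera adjusted p = 0.0352, and adjusted p = 0.177 with an estimated correlation; median -0.13), with 6 of 25 passing lower. The epoxide hydrolase gene Ephx2 had -0.57 ± 0.08 (edgeR adjusted p = 1.36e-05). That list was lost without tg_female 4 (adjusted p = 0.0557), tg_male 2 (0.110) or tg_male 3 (0.0634).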

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

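The tests of the Cyp2b counts, of the clock arms, of single libraries and of feeding genes in this part were chosen only after the result was seen.

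Counts of Cyp2b10, Cyp2b19 and Cyp2b23 were near 0 in Cyp2b-null livers and low but present in hCYP2B6-Tg livers; the labels do not say which mouse Cyp2b genes hCYP2B6-Tg mice keep. Less depth in the Cyp2b-null libraries was excluded: at the rate of hCYP2B6-Tg livers 161.8 counts were predicted against 3 seen (one-sided Poisson probability 3.72e-65, which covers counting error only), and every Cyp2b-null library had 0 or 1 where the hCYP2B6-Tg libraries had 6 to 50. Reads of one other transcript, such as human CYP2B6, assigned to the 3 mouse genes might explain the pattern, since a single source would keep 1 ratio of the 3 genes in all hCYP2B6-Tg libraries. The ratio did not differ detectably (Monte Carlo chi-square p = 0.210), but the lowest predicted count was only 1.61, so this cannot be told apart from low expression of the mouse genes themselves. A test against the human sequence was not made here, and a biological difference in the genotype remains open.

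The circadian list was higher in hCYP2B6-Tg livers of both sexes by camera, but not with an estimated correlation (adjusted p = 0.599 in females and 0.499 in males). The preset camera call in females did not rest on null_female 1 alone, since the adjusted p was 0.00203 without it. Because that call did not hold with an estimated correlation, null_female 1 is not excluded as a cause of the difference in females. The difference between the arm of Per, Dbp, Tef, Hlf and Ciart (7 genes) and the arm of Arntl and Clock (2 tested genes) was higher in hCYP2B6-Tg livers by 1.22 on the log2 scale (exact permutation within sex, two-sided p = 0.00327). By sex the arm difference was 1.12 in females (exact p = 0.114) and 1.33 in males (exact p = 0.0286), and without null_female 1 it was 0.58 in females (exact p = 0.20) and 0.95 over both sexes (exact p = 0.00612). This is what another phase of the clock at collection would give, and it may come from the genotype or from the hour at which each group was collected, which the labels do not state.

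Lipogenesis genes had lower estimates in hCYP2B6-Tg females and higher ones in hCYP2B6-Tg males, with a mean effect on log2 CPM of -0.30 and 0.49. With all female libraries the exact permutation p of the female effect was 0.314, so that test did not show a fall in females. Whether the camera call in females rests on library tg_female 4 alone, with the lowest lipogenesis score, cannot be told. Without it the list did not pass by camera (adjusted p = 0.301) and the female effect was -0.12. The SD was then 0.29 in hCYP2B6-Tg and 0.37 in Cyp2b-null females (0.42 and 0.37 with it). The list was lost as well without null_female 5 (0.407; effect -0.15), so 3 against 4 libraries cannot decide. Another feeding state at collection would likely move the fasting genes Pck1, G6pc, Igfbp1, Ppargc1a, Pdk4 and Irs2 the opposite way. Their difference between the sexes was 0.02 (exact permutation, two-sided p = 0.946), which neither shows nor excludes a difference in feeding. A biological response of lipid synthesis to CYP2B6 that depends on sex stays open.

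The genotype effect differed between the sexes, female minus male, by -1.38 for Ccdc141, -1.30 for Rasgef1b, -1.35 for Wipf3, 1.92 for E2f8, 1.42 for Pim1 and 1.07 for Ablim3 in log2 units (edgeR test of the difference itself). Mean genotype effects of 12 lists differed by camera with the preset correlation only, since 0 of them passed with an estimated correlation (lowest adjusted p = 0.499) or fry. The differences were -0.78 for lipogenesis, -0.30 for cholesterol synthesis, -0.15 for gluconeogenesis, glycolysis and insulin signalling, -0.13 for oxidative phosphorylation and -0.23 for fibrosis. They were 0.43 for the unfolded protein response, 0.43 for heat shock proteins, 0.71 for male-biased genes, -0.16 for hepatocyte markers, 0.25 for pericentral genes, -0.28 for periportal genes and -0.25 for endothelial markers. Heat shock proteins, endothelial markers, pericentral genes, gluconeogenesis, fibrosis and hepatocyte markers were lost by camera without single libraries, hepatocyte markers in 8 of the 16 omissions.

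A single library lay far from the other 3 of its group in 18 of 302 groups tested, where chance marks about 1 in 20 groups, or about 15.1 here. In null_male 1 these were Cyp2a22 (10.3 CPM, others 4.06 to 4.95), Tnk2os (2.17 CPM, others 1.58 to 1.65), E2f8 (15.7 CPM, others 21.9 to 22.6) and Eif2s3y (41 CPM, others 54.8 to 57.6). In tg_male 4 they were Cyp2a22 (18.7 CPM, others 6.15 to 6.53), Fitm1 (71.4 CPM, others 52.2 to 54.8) and the mean log2 CPM of cholesterol synthesis genes (7.21, others 7.58 to 7.62). Library tg_female 1 had 10.8% of its counts on Alb (others 8.75 to 9.09) and 14.3 CPM of E2f8 (others 21.9 to 22.4). Library tg_female 4 had 50.9 CPM of Chordc1 (others 62.1 to 63.9) and 128 CPM of Sult3a1 (others 31.5 to 46.7). In null_female 3 they were Hspb1 (7.17 CPM, others 4.58 to 4.92) and Slco1a4 (283 CPM, others 183 to 188). The remaining 5 were tg_female 5 with 20.9% of counts on its 10 highest genes (others 22.8 to 23.1), tg_male 2 with a mean log2 CPM of clock genes of 5.12 (others 4.80 to 4.85), tg_female 2 with 10.9 CPM of Ccdc141 (others 12.4 to 12.6), tg_male 3 with 855 CPM of Mup7 (others 484 to 540) and null_male 2 with 126 CPM of Clec4f (others 99.2 to 103).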

How the results depend on the processing

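Leaving out the ribosomal RNA rows, leaving out null_female 1, null_female 3 and tg_male 4 together, and all alternatives and splits for lists in the comparisons of sex and of the difference between the sexes were chosen only after the result was seen, and the 3 libraries were picked by eye. By the count of values far from the rest of the group they were not the farthest: null_male 1 had 4, tg_male 4 had 3, null_female 3 had 2 and null_female 1 had 0.

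The count of 0 genes in females was 3 without a filter (Marveld1 higher, Fam160a1 and St5 lower) and 10 with DESeq2, and 0 to 1 leaving out a library (1 without null_female 1 or tg_female 1). The 15 genes in males became 44 with DESeq2 (12 shared), 6 with limma voom (6 shared), 25 with quality weights (13 shared), 9 without robust estimation (8 shared), 27 with only the 2 groups fitted (13 shared), 28 without the 3 libraries (11 shared), 24 at an adjusted p under 0.1, 5 at a log2 change of at least 1 (Ciart, Rasgef1b, Tnk2os, Egfr and Pms1), and 2 to 8 leaving out a library. The 6 genes that differed between the sexes became 0 with library totals only, 19 with DESeq2 (6 shared), 3 with limma voom (E2f8, Pim1 and, not among the 6, Egfr) and 0 to 12 leaving out a library. At a log2 change of at least 1, 345 and 386 genes differed by sex in Cyp2b-null and hCYP2B6-Tg livers. With library totals only the split between higher and lower moved from 7 and 8 to 3 and 9 in males, and from 632 and 749 to 773 and 605 for sex in hCYP2B6-Tg livers, while the median of all genes shifted by at most 0.039. Lists changed by genotype numbered 0 with an estimated correlation and 0 with fry in females, in males and in the difference between the sexes. In females the list count was 12 without the 3 libraries and 6 to 11 leaving out a library, and in males 6 to 13 leaving out a library. Lists differing by sex numbered 5 in Cyp2b-null and 6 in hCYP2B6-Tg livers with an estimated correlation, and 16 and 17 with fry (15 shared in each). Reversed estimates were found only for genes next to the Cyp2b genes, none called in any setting: in females Cyp2a22 was 0.020 without the 3 libraries, and leaving out a library gave -0.0048 to 0.45 for Cyp2a5, -0.015 to 0.057 for Cyp2a12 and -0.38 to 0.10 for Cyp2g1, and in males -0.029 to 0.49 for Cyp2g1. Leaving out a library lowers power by construction, yet some counts rose when a library was left out. The cause of those rises and of the other changes was not tested.

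With the number in the title as a block, 5 genes passed in females (Fzd8, Cyp2c44, Insig2, Clpx and Loxl4, named after their values were seen), 14 in males (3 of the 15 shared, Fnip2, Rhobtb1 and Egfr), 10 differed between the sexes (1 shared), and 574 (516 shared) and 767 (689 shared) differed by sex in Cyp2b-null and hCYP2B6-Tg livers. With the block Cyp2a4 (1.22, edgeR adjusted p = 0.00100) and Bhlhe40 (0.62, adjusted p = 0.0254) passed in males. Lists numbered 7 in females (3 of the 6 shared), 14 in males (10 of the 10), 8 in the difference between the sexes (8 of the 12), and 14 (13 of the 17) and 16 (16 of the 19) by sex in Cyp2b-null and hCYP2B6-Tg livers with the block. The block estimates reversed for Cyp2a12 (-0.0094), Cyp2f2 (-0.018) and Cyp2g1 (0.27) in females. Of 252 results, 214 kept their direction and side of the threshold with the block, 32 became weaker, 3 stronger and 3 reversed. In the genotype contrasts, correlations of residuals between libraries of one number were all small. They were -0.062 to 0.075 in females (mean -0.013, against 0.0030 for other pairs) and 0.039 to 0.052 in males (mean 0.045, against -0.010). With 3 such pairs in each sex, this neither shows nor excludes a weak pairing by number. The sex contrasts were not checked in this way. A library whose number has no partner in the other group drops out of a contrast with the block. For genotype these were null_female 3, tg_female 2, null_male 1 and tg_male 5, which left 3 same-number pairs per sex. For sex they were null_female 5, null_male 2, tg_female 1 and tg_male 3. Beyond this loss of libraries, why the calls changed with the block was not tested.

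Of 252 results, 250 kept their direction and side of the threshold with RLE scaling and 2 became weaker, and with no filter 240 kept theirs, 7 became weaker and 5 stronger. With DESeq2 168 of 180 results kept theirs and 12 became stronger, and with limma voom 174 of 188 kept theirs, 13 became weaker and 1 stronger. The DESeq2 tally leaves out results to which DESeq2 gave no adjusted p. Among these were Ciart, Tnk2os and Pms1 in males, which were thus not called by DESeq2. At a log2 change of at least 1, 159 of 188 kept theirs and 29 became weaker. Of 64 list results, 11 kept theirs with an estimated correlation and 53 became weaker, and with fry 30 kept theirs and 34 became weaker. Depth limits what a missing count means: a count of 0 in 1 library allows up to 0.537 CPM, and the Cyp2b genes lay near that limit. Every alternative chosen in advance was run.

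No other split of the same libraries gave as many as the 15 genes in males (highest other 1; 1 of 35 splits as large, the real one included). That is the smallest share 35 splits can give and was not adjusted over the patterns tested, so chance was not excluded. The same share was found for 1013 genes by sex in Cyp2b-null (highest other 2; 1 of 35) and 1381 in hCYP2B6-Tg livers (highest other 1; 1 of 35). There every other split puts both sexes on each side, which can widen the spread and lower the count. Those splits therefore cannot decide on chance for the genes by sex. For 6 lists in females (highest other 14; 19 of 35) and 10 lists in males (highest other 15; 6 of 35) other splits gave as many or more, so chance was not excluded. The splits cannot test the 0 genes in females (highest other 7; 35 of 35) or in both sexes (highest other 0; 100 of 100), since every split has at least 0. Nor do they test chance for the 17 lists by sex in Cyp2b-null (highest other 18; 3 of 35) and the 19 in hCYP2B6-Tg livers (highest other 20; 2 of 35), because the splits with as many lists hold 3 libraries of one sex against 1 and so still carry the sex difference. For the difference between the sexes, 3 of 100 drawn splits gave as many as the 6 genes (highest other 16) and 4 of 100 as many as the 12 lists (highest other 13). These shares are small, but chance was not excluded. A draw of 100 splits gives them only roughly, and other splits gave more than the real counts. None of the 12 lists passed with an estimated correlation, fry or exact tests of list scores. The splits with 7 genes in females and 16 in the difference may point to a structure of the samples other than genotype, which was not tested.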

Other observations

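The choice of genes in this part and the test of the folding lists were made only after the result was seen.

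Bile acid genes differed by sex beyond the genes named so far, and as a list they passed by camera in Cyp2b-null livers. The bile acid list was not among the 19 that passed by sex in hCYP2B6-Tg livers. Nor was it among the 12 lists whose genotype effect differed between the sexes, so no difference between the genotypes was shown. In Cyp2b-null livers the list was lost with a block for the number in the title (camera adjusted p = 0.111). The list of bile acid synthesis and transport was lower in Cyp2b-null females (camera adjusted p = 0.0173, adjusted p = 0.293 with an estimated correlation, and lost without null_female 5 at 0.0657 or null_male 1 at 0.0511), with 7 of 23 genes passing lower and 2 higher. The organic anion carrier gene Slco1a1 had -7.33 in females over males, and the hydroxylase genes Cyp7b1 and Cyp8b1 had -2.55 and -1.58. The related carrier gene Slco1a4 was higher in females, by 1.64. The clock list did not pass by sex in Cyp2b-null livers (camera adjusted p = 0.386), but 4 of its 19 genes did, 3 higher and 1 lower in females, among them Bhlhe41 at -2.88 ± 0.43 (edgeR adjusted p = 5.67e-05) and Arntl at 1.18 ± 0.35 (adjusted p = 0.0487).

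Protein folding scores also varied between livers of one group. The mean log2 CPM of unfolded protein response and heat shock genes was highest in tg_female 5 (6.89 and 6.11) and tg_female 2 (6.75 and 5.92) among females, and in null_male 3 (6.70 and 5.53) among males. Such livers may share a state of protein folding stress of either genotype. As a test, the 2 scores were taken as deviations from their group means and correlated over the 8 libraries of each sex, with r = 0.966 in females (permutation, two-sided p = 0.000298; rho = 0.952) and r = 0.841 in males (permutation p = 0.00657; rho = 0.786). Without the 2 farthest libraries r was 0.907 and 0.904, and permutation of such deviations is only approximate. The rise of both lists in hCYP2B6-Tg females is therefore a rise of genes that vary together, with tg_female 2 and tg_female 5 at the top of both. Other pairs of lists were not correlated, so whether this is particular to the folding lists is not known.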
